A study of Mus musculus with 12 samples.

How the data were processed

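The data were gene expression values from 12 Affymetrix arrays hybridized with RNA of MIN6 cells. Per the labels, 50000 cells per well were transfected with Hes3 siRNA or scrambled siRNA at 2 uM and assayed 12 to 24 hours later, and 250 ng of total RNA was labelled for each array. The labels also state that duplicate or quadruplicate samples came from a single experiment, and give no batch, date or RNA integrity value. Groups came from the sample titles: 2 arrays each for Hes3 siRNA and scrambled siRNA in CC, and 4 each in DC, where the replicate numbers of the arrays labelled Hes3 siRNA are 1, 2, 5 and 7.

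The deposited table holds 1 value per probe set and array on a log2 scale, for 35556 probe sets. No label states the unit: log2 is read from the values, which run from 3.94 to 14.4. The method of summarization, background correction and normalization by the authors is not given in the sources used here, and raw signals were not analysed here. All 12 columns were used, and 0 were left out. The platform annotation of 2016 gave 21789 probe sets exactly 1 gene symbol, 1621 several and 12146 none. Entrez identifiers of 21698 single-gene probe sets matched the reference gene table, and 0 symbols were updated. Where a gene had several single-gene probe sets (999 genes), the one with the highest mean over the 12 arrays stood for it, which left 19938 genes, with no filter on dim genes. Positions are not given, since the genome build of the reference was not matched to that of the arrays. Ins1, Gapdh and Cdkn1a, among other genes, were not analysed here.

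Differences were estimated with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), with 1 mean per group over all 12 arrays, 8 residual degrees of freedom and 7.62 prior degrees of freedom. There were 5 contrasts: the siRNA labels in CC and in DC, DC against CC for each siRNA label, and the difference of both siRNA contrasts. P-values are two-sided and were adjusted by the Benjamini-Hochberg method over all 19938 genes in each contrast, with a threshold of 0.05 and no minimum fold change. Fold changes are given with the standard error of the model, and group means with their SD. Summary measures of arrays and the Hes3 probe set were compared by two-sided exact permutation tests. The shares of regroupings in which 2 groups do not overlap are 33.3% for 2 against 2, 13.3% for 4 against 2 and 2.86% for 4 against 4. They are averages over regroupings. Where genes vary together, the share of genes in a single division can lie far from them.

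The comparisons, the threshold, the 26 gene lists, the rule for named genes and the alternatives below were fixed before the data were examined, except where stated. The rule named Hes3, Ins1, Ins2, Pdx1, Mafa and Hes1 in each comparison. It added the 10 largest increases and the 10 largest decreases among genes past the threshold whose arrays did not overlap, leaving out predicted, clone, microRNA, small nucleolar RNA and olfactory or vomeronasal receptor symbols. Where fewer than 5 passed in a direction, it added the 5 with the smallest p, given as values, and from each list up to 4 members past the threshold or, where none passed, 2 as values. The text prints part of the genes so named. Genes of lists made after the data were seen were chosen outside this rule.

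The lists held 510 entries, of which 472 were measured: beta cell identity, insulin granule and exocytosis, Notch pathway and Hes/Hey family, JAK/STAT3 pathway, Hedgehog pathway, S phase, G2/M and mitosis, cholesterol synthesis, fatty acid synthesis, hypoxia targets, glycolysis, serum response, ER stress and protein folding, ATF4 and amino acid response, interferon response, NF-kappaB genes, p53 targets, oxidative phosphorylation, neural progenitor markers, genes disallowed in beta cells, and markers of alpha cells, of delta, PP and epsilon cells, of acinar cells, of duct cells, of fibroblasts and matrix, and of macrophages and endothelium. Each was tested with camera in limma at its preset correlation of 0.01, adjusted over the 26 lists in each contrast, with camera at an estimated correlation and fry beside it. Members past the threshold were counted with p adjusted over all genes and adjusted over the list alone.

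Alternatives were quantile normalization, centring arrays on their median, leaving out genes under the 40th percentile of mean signal, eBayes with trend and robust settings, a fit on only the arrays compared, the mean of a gene's probe sets, all probe sets, array weights, replicate number as a block, a minimum of 1.5-fold, and leaving out each array in turn. Chosen after the data were seen were cyclic loess normalization, leaving out DC arrays 1 and 5 labelled Hes3 siRNA together, and 10000 random lists matched on signal level. Members of the random lists were drawn independently of each other. Their ranges take no account of correlation among the genes of a list and can be too narrow. Lists of BMP/SMAD target, ERK feedback and LXR target genes and a sorting of short RNA genes into classes were also made after the data were seen.

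Code was tested on simulated data with the group sizes and spread of these arrays. Of 100 genes given a change of 0.5 (log2), limma called 89 in the comparison of siRNA labels in DC, 75 in CC, 73 for culture with scrambled siRNA and 66 for culture in the arrays labelled Hes3 siRNA. Of 100 genes given a change of 1, it called 100, 97, 99 and 100, with 10, 10, 8 and 9 false calls. A shift of 0.3 in the 25 measured G2/M genes was called by camera in each of the 4 comparisons, with 0 other lists called. Genes were simulated independently of each other, whereas the estimated correlation of the G2/M list in the real arrays was 0.583. The simulation therefore cannot show how often limma, or camera at its preset correlation, makes false calls among correlated genes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with numpy 2.4.6 and pandas 2.3.3.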

Results

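RNA was measured on 12 Affymetrix arrays from MIN6 cells, a mouse insulinoma line that makes insulin and serves as a model of the pancreatic beta cell. The cells carried siRNA against Hes3, a transcriptional repressor of the Hes/Hey family, or a scrambled control siRNA. They were kept in serum medium at 20% oxygen (Classic Conditions, CC) or without serum at 5% oxygen (Defined Conditions, DC). Each siRNA had 2 arrays in CC and 4 arrays in DC, and 19938 genes were tested. Signals ran from 3.94 to 14.4 on the deposited log2 scale. The mean of the array medians was 7.83 in both CC groups, 7.94 in the DC arrays labelled Hes3 siRNA and 7.86 in the DC scrambled arrays. The number of arrays limits the precision. The labels describe samples from a single experiment, so each p-value measures only the spread between these samples, which can be technical.

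Hes3 itself (probe set 10518902) was not lower in the arrays labelled Hes3 siRNA. In CC its mean log2 signal was 7.22 ± 0.00523 (SD, n = 2) in those arrays and 7.02 ± 0.291 (SD, n = 2) in the scrambled arrays. The log2 fold change was 0.20 ± 0.109 (SE; limma adjusted p = 1). In DC the means were 7.34 ± 0.0609 (SD, n = 4) and 7.19 ± 0.0640 (SD, n = 4), and the log2 fold change was 0.15 ± 0.0767 (SE; limma adjusted p = 0.114). The arrays of the 2 DC groups did not overlap for Hes3, as for 40.9% of all genes. The two-sided exact permutation p for Hes3 was 0.0286 over 70 regroupings, the smallest this design allows. In CC the exact permutation p was 1 over 6 regroupings, of which 33.3% keep the groups from overlapping. The mean Hes3 signal over the 12 arrays was 7.22, at the 29.8th percentile of genes. With genes in 4 equal parts by signal level, the dimmest part, just below Hes3, had a median log2 fold change of 0.146 in DC. The higher Hes3 signal in DC thus cannot be told apart from the general shift of dim genes. The sign of the Hes3 difference turned in CC without CC scrambled array 2 (log2 fold change -0.006) and in DC under cyclic loess normalization (-0.02), an alternative chosen after the data were seen. Groups are therefore named by their label in what follows, and no direction is read as an effect of lower Hes3 mRNA.

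Apart from single genes, the 4 DC arrays labelled Hes3 siRNA had a narrower spread of signals than the 4 DC scrambled arrays. The SD over all probe sets was 1.79 ± 0.0186 (SD, n = 4) against 1.84 ± 0.0125 (SD, n = 4), with an exact permutation p of 0.0286 over 70 regroupings, and both CC groups had 1.87. The first principal component held 61% of the variance. DC arrays labelled Hes3 siRNA scored 34.8 (array 1), 15.6 (array 2), 29.2 (array 5) and 12.8 (array 7) on it, so arrays 1 and 5 lay farthest from the other groups. The CC scrambled arrays scored -7.96 and -32.8. Correlations between arrays of a group ran from 0.980 to 0.996. Those between arrays of different groups ran from 0.958 to 0.995, so the 2 ranges overlapped.

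**Figure D1:**
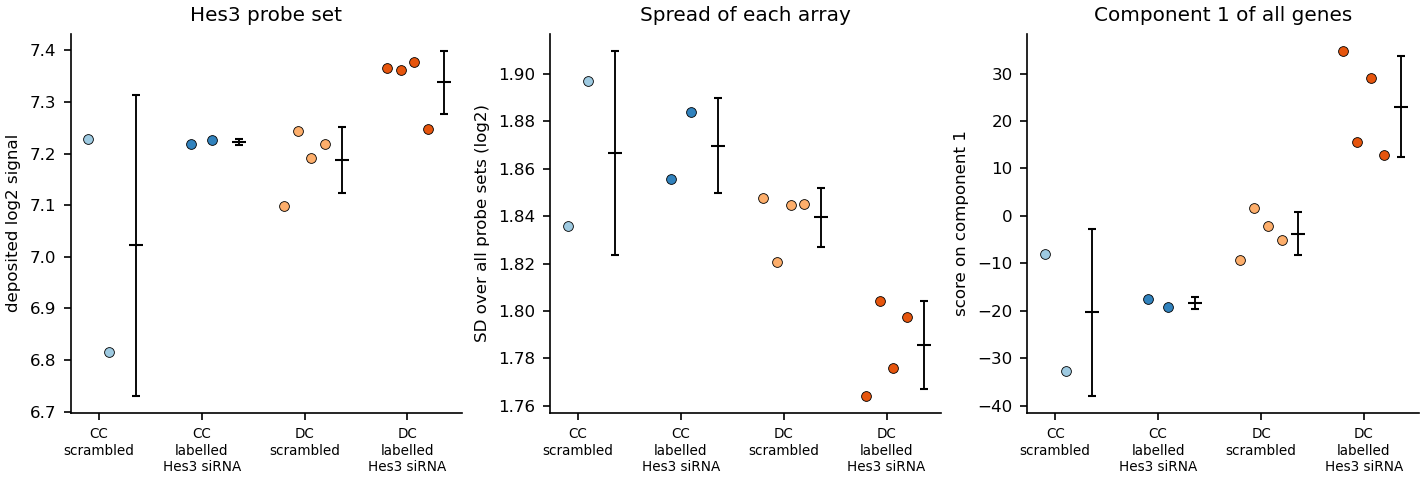
Each point is 1 array, grouped by culture (CC, DC) and siRNA label, with the group mean and SD as a bar; the panels show the log2 signal of Hes3, the SD of log2 signal over all probe sets and the score on the first principal component. Hes3 lay between 7.25 and 7.38 in the DC arrays labelled Hes3 siRNA and between 7.10 and 7.24 in the DC scrambled arrays, and the SD of array 1 (1.76) was the lowest of the 12 arrays.

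The comparison of siRNA labels in CC asked what Hes3 siRNA changed in serum medium at 20% oxygen, and here no single gene passed the test. Of all 19938 genes, 26.9% had CC arrays that did not overlap between the labels, where chance gives 33.3%. The genes with the smallest p included Mpv17l (log2 fold change 0.36 ± 0.0918 SE, 2 arrays against 2), Inhba, which encodes a subunit of activin (0.44 ± 0.118), and Cd200 (0.34). Among lower values were Ggt5 (-0.42 ± 0.0887), Ifi214 (-0.44), Tbl1xr1 (-0.32) and the host gene of several small nucleolar RNAs Gas5 (-0.53 ± 0.138). The beta cell genes Ins2 (0.01), Pdx1 (0.03) and Mafa (0.02) and the Notch target Hes1 (-0.06) lay near 0. All of these had a limma adjusted p of 1, and 415 of 19938 genes had an unadjusted p under 0.05. Of 26 gene lists, 7 passed camera at its preset correlation with 0 members past the test in any of them. With an estimated correlation their adjusted p ran from 0.447 to 0.926. Higher medians belonged to oxidative phosphorylation (log2 fold change 0.12, camera adjusted p = 0.000128), G2/M and mitosis (0.10, adjusted p = 0.0101), fibroblast and matrix markers (0.11), macrophage and endothelial markers (0.07) and cholesterol synthesis (0.06). Lower medians belonged to p53 targets (-0.05, camera adjusted p = 0.00279; 1 member fell when adjusted over the list alone) and insulin granule and exocytosis (-0.02). For the fibroblast, macrophage and endothelial, cholesterol and insulin granule lists the camera adjusted p was 0.0353. Without CC scrambled array 1 the medians turned to -0.04 for G2/M, -0.03 for cholesterol synthesis and -0.03 for oxidative phosphorylation. Without CC scrambled array 2 the fibroblast median turned to -0.03, and the calls of the macrophage and endothelial (0.02), insulin granule (0.007) and p53 (-0.09) lists were lost. Without CC array 2 labelled Hes3 siRNA, 2 of the 26 lists passed, and without CC array 1, 4 of them. In this comparison camera's direction differed in sign from the median for the Notch, JAK/STAT3, hypoxia, ER stress and interferon lists, none of which passed.

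The comparison of siRNA labels in DC asked the same in serum-free medium at 5% oxygen, with 4 arrays against 4. In the arrays labelled Hes3 siRNA, genes of mitosis were lower together: 21 of the 25 measured members of the G2/M list fell (23 when adjusted over the list alone) and 0 rose. The list passed camera (adjusted p = 2.55e-11), but not with an estimated correlation (adjusted p = 0.479). Examples were the spindle protein gene Hmmr (log2 fold change -0.75 ± 0.125 SE; 8.88 ± 0.160 against 9.63 ± 0.176, SD, n = 4), the cytokinesis regulator Ect2 (-0.60 ± 0.0986), the spindle checkpoint kinase Bub1 (-0.56 ± 0.0881) and the spindle protein Nusap1 (-0.54 ± 0.106). The largest decreases among single genes were of Scoc (-1.22 ± 0.216), the tight junction gene Cldn1 (-1.04 ± 0.141; 9.09 ± 0.384 against 10.1 ± 0.103, SD, n = 4), Edil3 (-0.98 ± 0.174) and Mzt1, a part of the gamma-tubulin complex (-0.97 ± 0.156). Next came the calcium-binding protein of endocrine cells Scgn (-0.93 ± 0.125), Mindy2 and Akr1c14 (-0.93 each), the adhesion gene Chl1 (-0.91 ± 0.132), and Hmgn5 and Ccnyl1 (-0.88 each). Increases were smaller, with Prp2 (0.62 ± 0.135), Pate11 (0.60 ± 0.0895), Krtap10-10 (0.58), Rnu7 (0.54), Pirb (0.51 ± 0.0808), Gpr6 (0.50 ± 0.0770) and the urothelial gene Upk2 (0.49) at the top. Limma adjusted p was 0.00302 for Scoc, 0.00168 for Cldn1 and Scgn, 0.0025 for Hmmr, 0.00186 for Pate11 and 0.00203 for Gpr6.

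Single genes of lipid synthesis and mitochondria also fell in the DC arrays labelled Hes3 siRNA, as did 2039 of the brightest 4984 genes. Cholesterol synthesis had 12 of 20 members lower (12 when adjusted over the list alone) and 0 higher, among them Idi1 (-0.83 ± 0.161), Hsd17b7 (-0.66 ± 0.118), Ebp (-0.51) and Nsdhl (-0.49). Of the fatty acid synthesis list, 7 of 15 members fell and 1 rose (7 and 1 when adjusted over the list alone), with the desaturase Scd1 at -0.40 ± 0.0932. Oxidative phosphorylation had 9 of 26 members lower (7 when adjusted over the list alone), including cytochrome c, Cycs (-0.51 ± 0.108), and Cyc1 (-0.35 ± 0.0748). The S phase list had 11 of 29 lower (9 when adjusted over the list alone), with Ccne2 (-0.48 ± 0.0906) and Rrm1 (-0.44 ± 0.0873). The ATF4 and amino acid list had 9 of 20 lower (9 when adjusted over the list alone), with the serine and glycine enzymes Shmt2 (-0.42 ± 0.0807) and Psat1 (-0.42 ± 0.0867). Camera adjusted p was 7.01e-05 for cholesterol synthesis and for oxidative phosphorylation, 0.000109 for S phase, 0.000547 for ATF4 and 0.00247 for fatty acid synthesis. None of these held with an estimated correlation: adjusted p = 0.479 for cholesterol synthesis and S phase, 0.527 for oxidative phosphorylation, 0.294 for ATF4 and 0.369 for fatty acid synthesis. The G2/M median of -0.37 lay outside the middle 95% of random lists matched on signal level (-0.23 to -0.07). The cholesterol median (-0.23, range -0.24 to -0.06), the oxidative phosphorylation median (-0.19, range -0.22 to -0.08) and the S phase median (-0.14, range -0.21 to -0.06) lay inside theirs. So did the ATF4 median (-0.17, range -0.21 to -0.04) and the fatty acid median (-0.18, range -0.22 to -0.03). After quantile normalization the S phase median moved to -0.02 and its call was lost (adjusted p = 0.0563 by camera), and after cyclic loess G2/M alone of all lists kept its call.

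Many markers of other cell types were higher in the DC arrays labelled Hes3 siRNA, as dim genes were in general. Of the genes in 4 equal parts by signal level, the dimmest part had a median log2 fold change of 0.15 and the brightest -0.15. Fibroblast and matrix markers had 9 of 13 members higher (9 when adjusted over the list alone), with Sparc (0.44 ± 0.0854) and the collagens Col1a1 (0.37 ± 0.0655) and Col5a1 (0.36). Acinar markers had 8 of 11 higher (9 when adjusted over the list alone), with the proteases Prss2 (0.32 ± 0.0748) and Cela2a (0.31). Duct markers had 5 of 7 higher (5 when adjusted over the list alone), with the keratin Krt7 (0.32 ± 0.0739). Macrophage and endothelial markers had 7 of 12 higher (10 when adjusted over the list alone), with the receptors Tek (0.29 ± 0.0655) and Csf1r (0.28 ± 0.0608). Delta, PP and epsilon markers had 4 of 7 higher (5 when adjusted over the list alone), with pancreatic polypeptide, Ppy (0.38 ± 0.0662). The Notch list had 12 of 31 members higher (9 when adjusted over the list alone), with Hes5 (0.37 ± 0.0892), Dtx1 (0.33 ± 0.0813) and Notch2 (0.28 ± 0.0603). Hes1 rose by 0.25 ± 0.0715 (limma adjusted p = 0.0144), a call lost with arrays centred on their median (0.17) and with quantile normalization (0.17). The NF-kappaB list had 6 of 16 higher and 1 lower (9 and 1 when adjusted over the list alone), with the chemokine Cxcl1 (0.42 ± 0.102). Camera adjusted p was 0.0051 for the fibroblast, 0.00572 for the acinar, 0.0153 for the macrophage and endothelial, 0.0406 for the duct and the Notch, 0.0408 for the NF-kappaB and 0.0434 for the delta, PP and epsilon list. With an estimated correlation the adjusted p was 0.537 for the Notch and NF-kappaB lists and 0.527 for the others. Against random lists matched on level, only the fibroblast median (0.30, range 0.04 to 0.25) and the acinar median (0.261, range 0.053 to 0.260) of these lists lay above the range. Both were highest in DC arrays 1 and 5 labelled Hes3 siRNA. Relative to the mean of the 12 arrays, the fibroblast median was 0.324 and 0.248 in arrays 1 and 5 against 0.129 and 0.062 in arrays 2 and 7, and the acinar median was 0.275 and 0.209 against 0.108 and 0.072. The duct (0.26), macrophage and endothelial (0.19), delta, PP and epsilon (0.19), Notch (0.15) and NF-kappaB (0.16) medians lay within theirs. Among calls that rested on 1 array, the Notch median was 0.11 without array 1 labelled Hes3 siRNA (adjusted p = 0.0511 by camera) and 0.15 without scrambled array 1 (adjusted p = 0.0615). The NF-kappaB median was 0.12 without array 1 labelled Hes3 siRNA (adjusted p = 0.0571), and the duct median was 0.28 without array 7 (adjusted p = 0.0516). The delta, PP and epsilon call was lost without any 1 of 7 arrays, at medians from 0.15 to 0.21. The macrophage and endothelial median turned to -0.09 with dim genes left out. Quantile normalization ended the calls of the NF-kappaB (0.10, adjusted p = 0.119 by camera), duct (0.165) and macrophage and endothelial lists (0.12, adjusted p = 0.121 each).

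Among beta cell genes in the same comparison, the transcription factor Neurod1 fell by 0.47 ± 0.0848 (log2, SE), and Il6st, Jak1 and Lifr of cytokine signalling fell by 0.39 ± 0.0700, 0.39 ± 0.0710 and 0.37 ± 0.0661. Pdx1 (-0.22, limma adjusted p = 0.0511), Mafa (-0.14, adjusted p = 0.156) and Ins2 (-0.05, adjusted p = 0.393) did not pass, and Ins1 was not analysed here. Of the beta cell identity list, 3 of 22 members rose and 4 fell (2 and 1 when adjusted over the list alone; median -0.10, camera adjusted p = 0.0406). It had an adjusted p = 0.479 with an estimated correlation, and the call was lost after quantile normalization (adjusted p = 0.587 by camera), without array 1 labelled Hes3 siRNA (-0.07) or without scrambled array 1 (-0.08). The beta cell identity median lay inside the middle 95% of random lists matched on signal level (-0.195 to -0.04). Of the ER stress list, 4 of 23 members fell (1 when adjusted over the list alone; median -0.03, camera adjusted p = 0.0434), among them the chaperone cofactor Dnajb9 (-0.66 ± 0.161). It had an adjusted p = 0.68 with an estimated correlation, and the call was lost after quantile normalization (0.01, adjusted p = 0.758 by camera) and without any 1 of 6 arrays (medians -0.06 to -0.01). The ER stress median lay above the middle 95% of random lists matched on signal level (-0.211 to -0.07). Relative to genes of like signal the list was therefore not lower. Lists that did not pass camera included insulin granule (2 higher and 5 lower of 30, adjusted p = 0.0762), Hedgehog (6 higher of 13, adjusted p = 0.106), and JAK/STAT3 (5 higher and 5 lower of 20, adjusted p = 0.736). Nor did p53 targets (5 higher and 6 lower of 16, adjusted p = 0.272), hypoxia (6 higher and 2 lower of 24, adjusted p = 0.736), glycolysis (1 each of 13, adjusted p = 0.143) and serum response (8 higher and 4 lower of 26, adjusted p = 0.453). For JAK/STAT3 and p53 targets the median was above 0 and camera's direction was down.

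In all, 9408 of 19938 genes passed limma in this comparison, 5769 higher and 3639 lower, with a median absolute log2 fold change of 0.27. Of these, 196 differed by at least 1.5-fold, 4 higher and 192 lower. That number was 122 without array 5, 314 without array 2 and 36 without arrays 1 and 5 labelled Hes3 siRNA. Of all 19938 genes, called or not, the 4 arrays of each label did not overlap for 8145 (40.9%), where chance gives 2.86% on average over regroupings. Genes vary together, with 61% of the variance on the first component, so this excess is not one of separate genes. Log2 fold change fell with signal level across genes, which are not independent replicates (Pearson r -0.503). The count was 5735 after quantile normalization and 5436 with dim genes left out. It was 5754 without scrambled array 1, 5881 without array 5 and 6064 without array 1 labelled Hes3 siRNA, and 331 without arrays 1 and 5 together, an alternative chosen after the data were seen. Cldn1, Edil3, Mzt1, Scgn, Mindy2, Akr1c14, Chl1, Neurod1, Ect2, Bub1, Shmt2, Pate11, Pirb and Gpr6 still passed without arrays 1 and 5, and Scoc (-0.86 ± 0.225), Hmmr (-0.65 ± 0.154), Nusap1 (-0.47 ± 0.133) and Idi1 (-0.63 ± 0.184) kept their direction but did not pass. Of all 122 named genes with a call in this comparison, 21 kept it without these arrays and 101 lost it. Over the 9408 genes the median fold change in the direction called was 0.266 with all arrays and 0.189 without these 2, and the median SE was 0.0748 and 0.0798. With arrays centred on their median 36.7% of the called genes were higher, against 61.3% on the deposited scale.

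**Figure D2:**
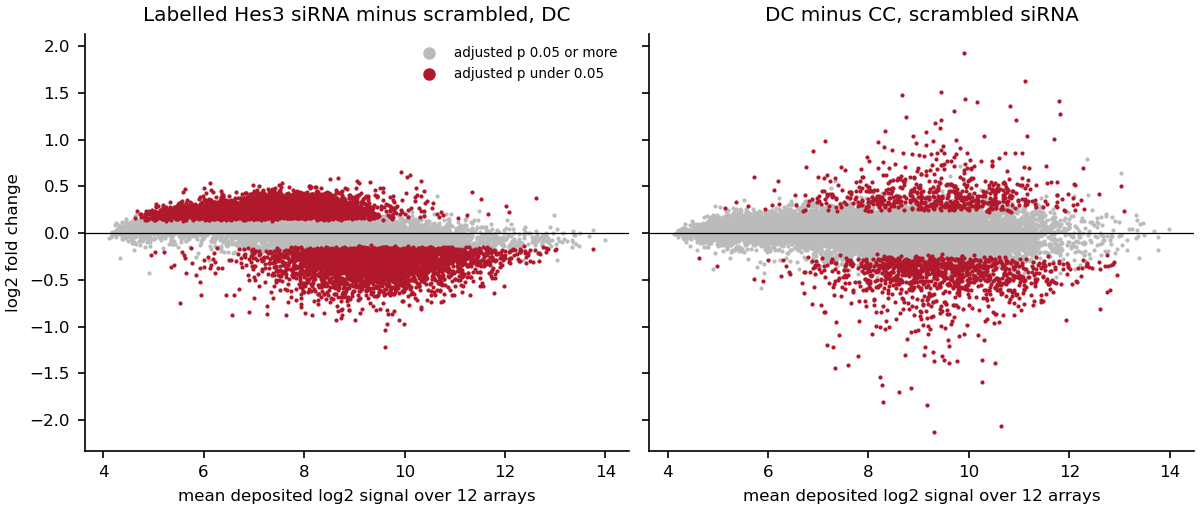
Each point is 1 gene, with its mean log2 signal over the 12 arrays on the horizontal axis and its log2 fold change on the vertical axis, red where the limma adjusted p was under 0.05; the panels show the siRNA labels compared in DC and the culture conditions compared with scrambled siRNA. Fold change fell with level more steeply in the first panel (r -0.503) than in the second (r -0.172).

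The comparison of culture conditions with scrambled siRNA asked how cells in serum-free medium at 5% oxygen (4 arrays) differed from cells in serum medium at 20% oxygen (2 arrays), with medium, serum and oxygen changing together. Genes of cholesterol synthesis were higher in DC: 19 of 20 measured members rose (19, with 1 lower, when adjusted over the list alone). Hmgcs1, which makes HMG-CoA for the mevalonate pathway, rose 3.81-fold (log2 10.7 ± 0.0727, SD, n = 4, against 8.75 ± 0.264, SD, n = 2; log2 fold change 1.93 ± 0.143 SE). The isomerase Idi1 rose 2.84-fold, the sterol dehydrogenase Nsdhl 2.71-fold and the lanosterol synthase Lss 2.64-fold. Fatty acid synthesis rose with it in 9 of 15 members (10, with 1 lower, when adjusted over the list alone): Scd1 (1.62 ± 0.114), fatty acid synthase Fasn (1.28 ± 0.106), the acetate-activating enzyme Acss2 (1.13 ± 0.0895) and Srebf1, a transcription factor of lipid synthesis (0.86 ± 0.0815). Lower in DC were Id1 (-1.81 ± 0.0968; 7.58 ± 0.0474, SD, n = 4, against 9.39 ± 0.235, SD, n = 2), Id2 (-2.13 ± 0.207) and Id3 (-1.44 ± 0.127), inhibitors of basic helix-loop-helix factors, and Dusp6, a phosphatase that acts on ERK (-1.84 ± 0.143). Agt, which encodes angiotensinogen, was 4.18-fold lower (-2.07 ± 0.20).

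Other increases in this comparison were of Tnr (1.48 ± 0.117), the imprinted gene Nnat (1.42 ± 0.216), the synaptic vesicle gene Sv2b (1.36 ± 0.152) and Olfml3 (1.31 ± 0.141). Other decreases were of Cltrn (-1.70), the receptors Tacr3 (-1.65 ± 0.140) and Cckbr (-1.59 ± 0.117), Ccdc80 (-1.62) and Csn3 (-1.54). Limma adjusted p was 1.26e-06 for Hmgcs1, 9.45e-07 for Scd1, 3.37e-07 for Lss, 2.73e-06 for Fasn, 4.07e-08 for Id1, 1.13e-05 for Id2, 1.82e-06 for Dusp6 and 1.08e-05 for Agt. Camera adjusted p was 1.91e-32 for cholesterol synthesis and 9.42e-12 for fatty acid synthesis, and both held with an estimated correlation (adjusted p = 0.0124 and 0.00756).

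**Figure D3:**
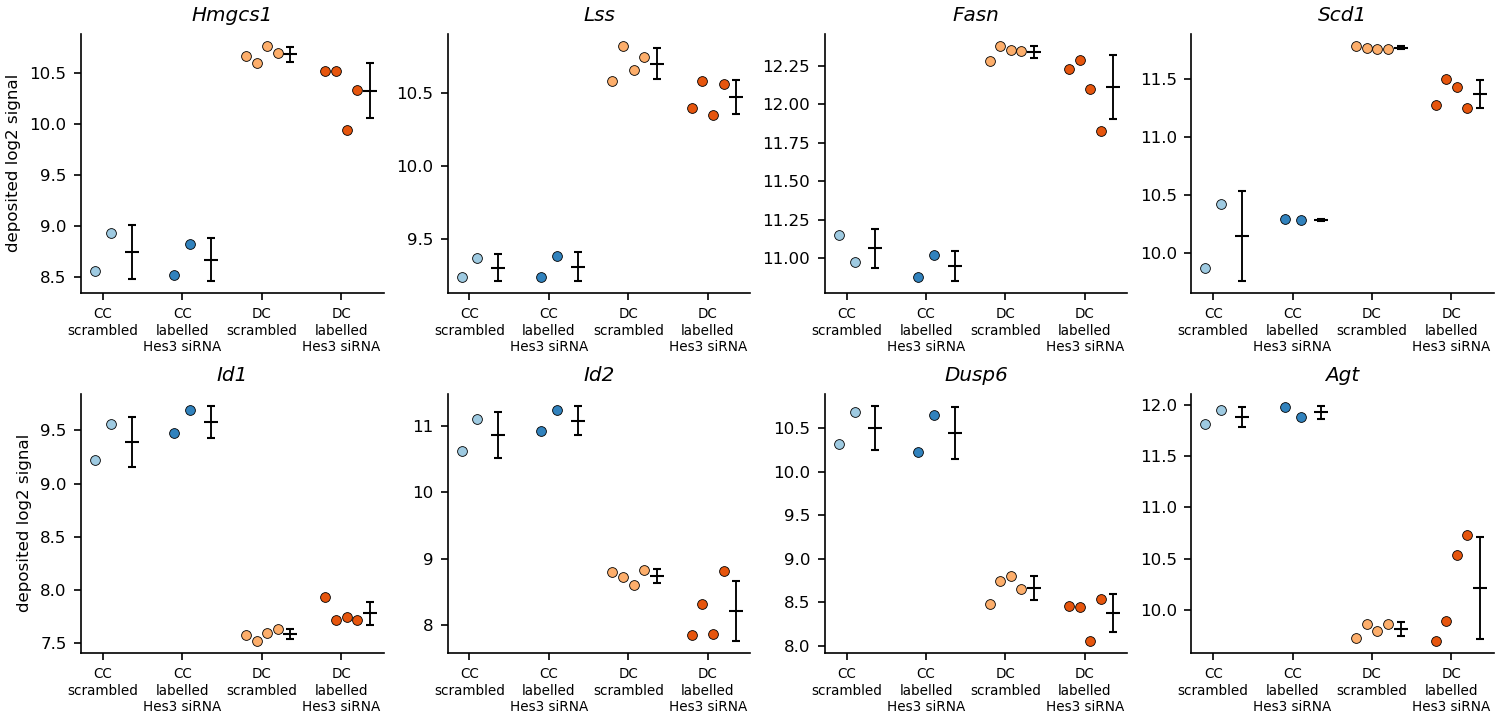
Each point is 1 array, with deposited log2 signal on the vertical axis for 8 genes in the 4 groups and the group mean and SD as a bar. Hmgcs1 lay between 9.94 and 10.8 in the 8 DC arrays and between 8.53 and 8.94 in the 4 CC arrays, and Id1 lay between 7.52 and 7.94 in DC and between 9.23 and 9.69 in CC.

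Part of the stress response genes were lower in DC with scrambled siRNA. Of the ATF4 and amino acid list, 9 of 20 members fell (16 when adjusted over the list alone), with the cystine transporter Slc7a11 (-1.02 ± 0.0957), the stress gene Nupr1 (-0.94 ± 0.111) and the amino acid transporter Slc7a1 (-0.50) as examples. Of the p53 targets, 8 of 16 fell and 1 rose (10 and 1 when adjusted over the list alone), with Plk2 (-1.41 ± 0.143), Mdm2, which restrains p53 (-0.87 ± 0.128), and Ccng1 (-0.66 ± 0.105). The medians were -0.33 and -0.30, camera adjusted p was 3.77e-13 and 1.37e-07, and both calls held with an estimated correlation (adjusted p = 0.0056 and 0.0134). Of the ER stress list, 14 of 23 fell (17 when adjusted over the list alone; median -0.38, camera adjusted p = 1.3e-13), including the chaperone cofactors Dnajc3 (-0.96 ± 0.131) and Dnajb11 (-0.77). It had an adjusted p = 0.216 with an estimated correlation. The serum response list had 6 of 26 lower and 1 higher (8 and 1 when adjusted over the list alone), with Dusp1 (-0.86 ± 0.104), Jun (-0.755 ± 0.0981) and Fos (-0.64 ± 0.102). Its median was -0.03, inside the range of random lists matched on level (camera adjusted p = 0.0145; adjusted p = 0.382 with an estimated correlation), and the call was lost without CC scrambled array 1 (adjusted p = 0.126 by camera). Of the JAK/STAT3 list, 3 of 20 fell and 1 rose (3 and 1; median -0.11, camera adjusted p = 0.00998), with Socs2 at -0.66 ± 0.0824. The adjusted p was 0.318 with an estimated correlation. This call was lost without CC scrambled array 2 (-0.13, adjusted p = 0.072).

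Glycolysis genes rose in 5 of 13 measured members (7 when adjusted over the list alone; median 0.38, camera adjusted p = 6.83e-05, adjusted p = 0.318 with an estimated correlation), with lactate dehydrogenase Ldha (1.21 ± 0.227) and the aldolase Aldoc (1.09 ± 0.150). The hypoxia list as a whole did not pass (2 of 24 rose and 3 fell, 2 and 5 when adjusted over the list alone; camera adjusted p = 0.896), and its median of 0.01 differed in sign from camera's direction. Pdk1, which inhibits pyruvate dehydrogenase (0.76 ± 0.138), and Ndrg1 (0.52 ± 0.0884) rose, whereas Ero1a (-0.53 ± 0.118) and Ddit4 (-0.47 ± 0.0851) fell, calls lost without CC scrambled array 2 (-0.41 and -0.38). Cell cycle lists went opposite ways. G2/M had 8 of 25 members higher (12 when adjusted over the list alone; median 0.26, camera adjusted p = 1.37e-07), with the kinesin Kif23 (0.70 ± 0.128) and Cenpf (0.44). S phase had 6 of 29 lower (9; median -0.20, adjusted p = 1.43e-06), with the ribonucleotide reductase gene Rrm2 (-0.79 ± 0.122). The adjusted p was 0.323 and 0.263 with an estimated correlation. The G2/M call was lost without CC scrambled array 1 (0.09) and the S phase call without CC scrambled array 2 (-0.08).

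Among islet genes, Isl1, a transcription factor of endocrine cells (0.59 ± 0.0987), the zinc transporter of insulin granules Slc30a8 (0.54 ± 0.0772), and Sytl4 (0.89 ± 0.112) and Pclo (0.73 ± 0.101) of exocytosis rose in DC with scrambled siRNA. The granule protein Chgb fell (-0.45). The beta cell identity list had 4 of 22 members higher (5 when adjusted over the list alone; median 0.08, camera adjusted p = 0.00352, adjusted p = 0.216 with an estimated correlation), a call lost without CC scrambled array 1 (0.07, adjusted p = 0.126 by camera). Ins2 (0.03), Pdx1 (0.06) and Mafa (0.21, limma adjusted p = 0.269) did not pass. Hes1 was lower (-0.32, limma adjusted p = 0.0323), a call lost without any 1 of 5 arrays (-0.34 to -0.30). Hes3 did not pass (0.17), its value being 0.37 without CC scrambled array 1 (adjusted p = 0.0141 by limma) and -0.04 without CC scrambled array 2. Glucagon, Gcg (-0.93 ± 0.116), and transthyretin, Ttr (-0.81 ± 0.143), fell, but the alpha cell list did not pass (2 of 6 fell, 2 when adjusted over the list alone; median -0.04, camera adjusted p = 0.0752). The other lists did not pass either: the insulin granule list (2 higher and 2 lower of 30, adjusted p = 0.785), the Notch list (1 higher and 4 lower of 31, adjusted p = 0.785), and the disallowed genes (1 higher and 2 lower of 11, adjusted p = 0.347). Single members passed among interferon (1 higher of 22, adjusted p = 0.896), Hedgehog (1 higher of 13, adjusted p = 0.347), neural progenitor (1 higher of 14, adjusted p = 0.26), fibroblast (1 higher of 13, adjusted p = 0.335), acinar (1 lower of 11, adjusted p = 0.859) and macrophage and endothelial markers (1 lower of 12, adjusted p = 0.924). In 4 further lists 0 members passed limma: NF-kappaB (adjusted p = 0.347), oxidative phosphorylation (adjusted p = 0.347), delta, PP and epsilon (adjusted p = 0.596) and duct markers (adjusted p = 0.896). For the Notch and acinar lists and the macrophage and endothelial list, the median was above 0 and the mean below 0.

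With scrambled siRNA, 1702 genes passed limma between the culture conditions, 616 higher and 1086 lower in DC, and 347 of them differed by at least 1.5-fold, 112 higher and 235 lower. Without CC scrambled array 1 this was 614, 111 higher and 503 lower, and without CC scrambled array 2 it was 284, 134 higher and 150 lower. Of all 19938 genes, called or not, 27.9% had 4 DC arrays that did not overlap the 2 CC arrays, where chance gives 13.3%. The count was 742 without CC scrambled array 2, 2364 without CC scrambled array 1 and 1054 with array weights.

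The same culture comparison in the arrays labelled Hes3 siRNA had 4 DC arrays against 2 CC arrays. Genes of lipid synthesis rose in DC here too, with Hmgcs1 at 3.14-fold (log2 fold change 1.65 ± 0.143 SE; 10.3 ± 0.271, SD, n = 4, against 8.67 ± 0.210, SD, n = 2), Lss (1.17 ± 0.0899), Fasn (1.16 ± 0.106), Scd1 (1.08 ± 0.114) and Insig1, a sterol sensor (0.90). Of the cholesterol list 14 of 20 members rose and 1 fell (14 and 1 when adjusted over the list alone), and of the fatty acid list 8 of 15 rose and 2 fell (8 and 2). Unlike with scrambled siRNA, neither list passed with an estimated correlation (adjusted p = 0.335 and 0.318). Lower in DC were Id2 (-2.87 ± 0.207), Tacr3 (-2.39 ± 0.140), Ly96 (-2.23 ± 0.256), Cltrn (-2.17), Dusp6 (-2.07 ± 0.143), the calcium buffer Calb1 (-1.96 ± 0.194), Cckbr (-1.81), Id1 (-1.81 ± 0.0968) and Slc35g2 (-1.74). Fras1 (1.05), the insulin receptor-related gene Insrr (1.03 ± 0.103), Tnr (0.95) and Ldha (1.02 ± 0.227) rose, the last a call lost without CC array 2 labelled Hes3 siRNA (0.96). Limma adjusted p was 2.12e-06 for Hmgcs1, 4.43e-07 for Id2, 3.75e-07 for Dusp6, 4.28e-08 for Id1 and 0.0038 for Ldha.

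In the arrays labelled Hes3 siRNA the ATF4 and amino acid list fell in 18 of 20 members (18 when adjusted over the list alone; median -0.59), with Slc7a11 (-1.33 ± 0.0957), Psat1 (-1.08 ± 0.106) and Shmt2 (-1.01 ± 0.0988). It held with an estimated correlation (camera adjusted p = 2.1e-12 and adjusted p = 0.00602). S phase fell in 19 of 29 (21 when adjusted over the list alone), with Rrm2 (-1.20 ± 0.122), the replication factor Rfc4 (-1.17 ± 0.166) and Pcna (-0.62 ± 0.104). ER stress fell in 16 of 23 with 1 higher (18 and 1 when adjusted over the list alone), with Dnajb9 (-1.59 ± 0.198) and Xbp1 (-0.78). Oxidative phosphorylation fell in 18 of 26 (20 when adjusted over the list alone), with Cycs (-0.77 ± 0.132) and Cyc1 (-0.61 ± 0.0916). Of the p53 targets 7 of 16 fell and 1 rose (8 and 1 when adjusted over the list alone), with Ccng1 (-0.96 ± 0.105) and Mdm2 (-0.92 ± 0.128). Fibroblast markers rose in 5 of 13 (5; median 0.23). G2/M fell in 11 of 25 (11; median -0.19), with Ccna2 (-0.61 ± 0.107), Bub1 (-0.57 ± 0.108) and Cdk1 (-0.52 ± 0.105), but its median moved to -0.04 after quantile normalization and the call was lost. Camera adjusted p was 7.26e-10 for S phase, 1.78e-09 for ER stress, 2.1e-08 for oxidative phosphorylation, 2.27e-07 for cholesterol synthesis and 0.00138 for G2/M. It was 0.00317 for p53 targets, 0.00891 for fatty acid synthesis and 0.0198 for fibroblast markers, the last lost after quantile normalization (0.17, adjusted p = 0.0691). With an estimated correlation the adjusted p was 0.283 for S phase and p53 targets, 0.411 for ER stress and 0.467 for oxidative phosphorylation. It was 0.7 for G2/M and fibroblast markers. Against random lists matched on level, the oxidative phosphorylation (-0.32), G2/M and fibroblast medians lay inside the middle 95%. Gcg (-1.05) and Ttr (-0.69) fell here too. Ins2 (-0.04), Pdx1 (-0.18, limma adjusted p = 0.166), Mafa (0.04) and Hes1 (-0.02) did not pass.

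In the arrays labelled Hes3 siRNA, 7986 genes passed limma between the culture conditions, 4231 higher and 3755 lower in DC, and 1103 differed by at least 1.5-fold, 73 higher and 1030 lower. The 4 DC arrays did not overlap the 2 CC arrays for 61.8% of all 19938 genes, called or not, where chance gives 13.3%. Centring arrays on their median moved the median of all genes from 0.09 to -0.02 and the share of called genes that were higher from 53% to 17.3%. The count was 2357 without CC array 2 and 3410 without CC array 1 labelled Hes3 siRNA, 5025 after quantile normalization, and 3631 without DC arrays 1 and 5 labelled Hes3 siRNA.

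Culture effects in the 2 siRNA labels, measured on different arrays, correlated across genes (Pearson r 0.694, Spearman rho 0.589; genes are not independent replicates). Hmgcs1, Lss, Fasn and Scd1 were among the 367 genes higher in DC under both labels, where independent calls would give 130.7. Id1, Id2, Dusp6, Tacr3 and Cckbr were among the 959 lower under both, where independent calls would give 204.5, and 2 genes passed in opposite directions. Of the 1702 genes called with scrambled siRNA, 96.1% had the same sign in the arrays labelled Hes3 siRNA. The effects of the siRNA label in CC and DC correlated less (Pearson r 0.261, Spearman rho 0.305). Without CC scrambled array 2 these correlations were 0.287 for culture and -0.381 for the siRNA label, and without CC scrambled array 1 the second was 0.717.

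**Figure D4:**
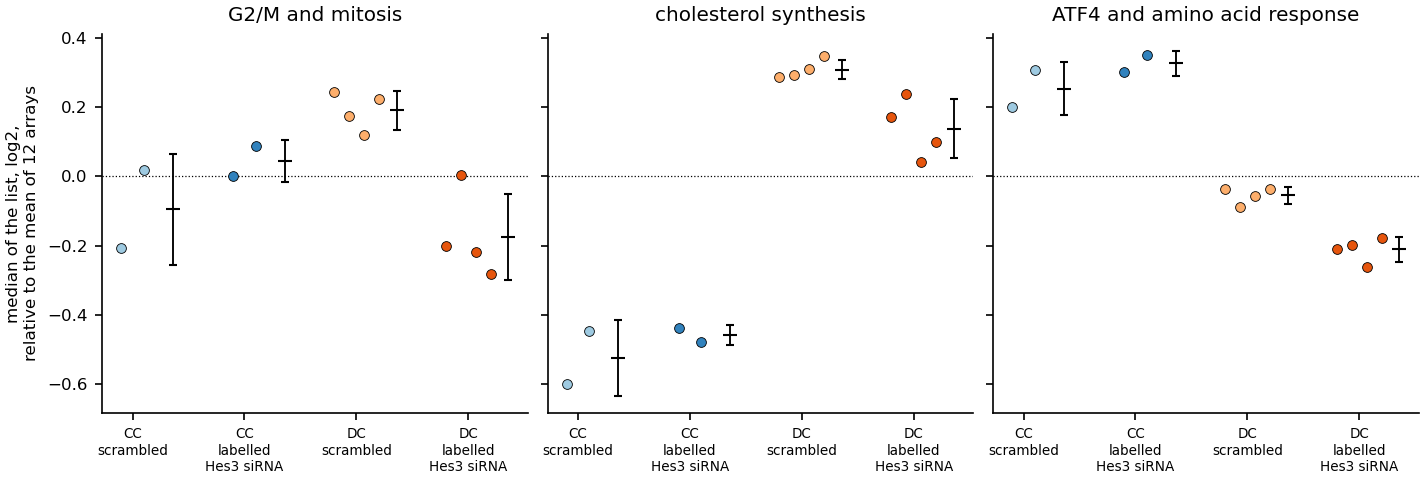
Each point is the median of a gene list in 1 array, in log2 units relative to the mean of the 12 arrays for each gene, for G2/M, cholesterol synthesis and ATF4 and amino acid genes, with the group mean and SD as a bar. The cholesterol medians lay between 0.04 and 0.35 in DC and between -0.60 and -0.44 in CC, and the G2/M medians between -0.28 and 0.003 in the DC arrays labelled Hes3 siRNA and between 0.12 and 0.24 in the DC scrambled arrays.

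Whether the siRNA label had a different effect in DC than in CC was tested as the difference of both effects, and no single gene passed. The smallest p-values belonged to Smpdl3a (-0.85 ± 0.133 SE), the biotin-recycling enzyme gene Btd (-0.83), the selenium carrier gene Selenop (-0.79), Eri2 (-0.71) and Xk (-0.60). Higher were Ifi214 (0.66 ± 0.135), Gsto2 (0.49), Atg9b (0.58), Fcer1g (0.40) and Azgp1 (0.49). All 10 had a limma adjusted p of 0.177. Ect2 (-0.83 ± 0.171), Idi1 (-1.17 ± 0.279), Hes3 (-0.05), Pdx1 (-0.24), Mafa (-0.16), Ins2 (-0.06) and Hes1 (0.30) did not pass. Unadjusted p was under 0.05 for 3471 of 19938 genes. Without CC scrambled array 2, 2056 genes passed, 491 higher and 1565 lower.

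Of the 26 lists, 8 differed between the culture conditions in their response to the siRNA label by camera. The difference was -0.46 for G2/M (adjusted p = 3.57e-17; 21 of 25 members when adjusted over the list alone), -0.29 for cholesterol synthesis (6.78e-08; 9 of 20), -0.26 for oxidative phosphorylation (6.94e-10; 8 of 26) and -0.18 for ATF4 and amino acid genes (1.84e-05; 3 of 20). It was -0.15 for S phase (1.84e-05), -0.12 for fatty acid synthesis (0.00195), -0.11 for beta cell identity (0.0486) and 0.14 for the Notch list (0.0405). None held with an estimated correlation, where the adjusted p was 0.303 for G2/M and fatty acid synthesis, 0.349 for cholesterol synthesis, 0.112 for ATF4, 0.409 for oxidative phosphorylation, S phase and beta cell identity, and 0.761 for Notch. Fold changes fell with signal level here too (r -0.458), and the medians of S phase, fatty acid synthesis, ATF4, beta cell identity and Notch lay inside the middle 95% of random lists matched on level. Those of G2/M (-0.25 to -0.04), cholesterol synthesis (-0.26 to -0.03) and oxidative phosphorylation (-0.262 to -0.063, against -0.264) lay below it. The beta cell identity call was lost without any 1 of 9 arrays (medians -0.13 to -0.07) and the Notch call without any 1 of 4 (0.09 to 0.13). Quantile normalization ended the calls of S phase (-0.06, adjusted p = 0.0653 by camera), fatty acid synthesis (-0.02, adjusted p = 0.169) and beta cell identity (0.02, adjusted p = 0.821).

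**Figure D5:**
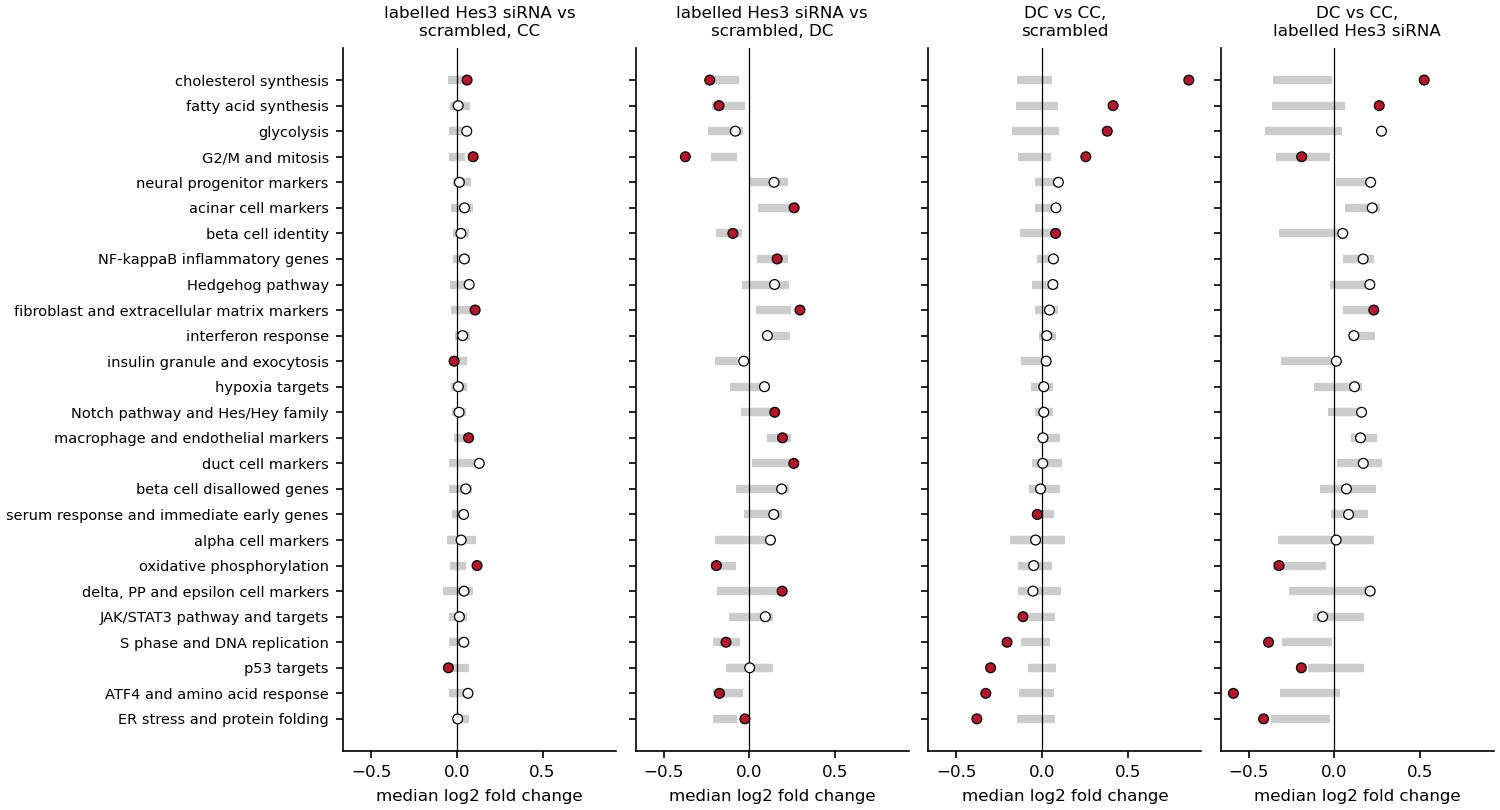
Each dot is the median log2 fold change of 1 of 26 gene lists in 1 of 4 comparisons, filled red where the camera adjusted p was under 0.05 at the preset correlation, and the grey bar is the middle 95% of random lists matched on signal level. In the comparison of siRNA labels in DC the G2/M median (-0.37) lay below its bar (-0.23 to -0.07), and in the culture comparison with scrambled siRNA cholesterol synthesis (0.86) lay above its bar (-0.15 to 0.06).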

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

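Of the tests in this part, the ones on leaving out DC arrays 1 and 5, on DC arrays divided so that none is shared, on the genes at least 1.5-fold lower, on random lists matched on level, on short RNA classes and on the Hes3 probe set were chosen only after the results they address were seen.

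The number of genes called between the siRNA labels in DC was the first pattern weighed: 9408 of 19938 genes passed limma in DC, against 0 in CC (415 at an unadjusted p under 0.05). DC had 4 arrays against 4 and CC had 2 against 2, with a larger SE. The test of the difference of both effects called 0 genes, so these counts do not show an effect confined to DC. A narrower signal range as the whole cause of the DC count was argued against by quantile normalization, which left 5735 genes past the threshold, although fold change still fell with level (r -0.244). Chance division of the arrays can be excluded only at the 0.05 level, for this experiment and for unselected arrays: 1 of the 35 splits of the 8 DC arrays, the real one, gave as many, the smallest share this design allows, and the highest of the others gave 0. The replicate numbers of the DC arrays labelled Hes3 siRNA (1, 2, 5 and 7) have gaps, and it is not known here whether arrays were left out. A choice of arrays by their signals would void the split and permutation tests. Arrays 1 and 5 as the only carriers of fold changes on the deposited scale are argued against by comparisons that share no array. Fold changes of arrays 2 and 7 rose with those of arrays 1 and 5 (slope 0.369 to 0.594, r 0.778 to 0.837). All genes entered, on a scale where fold change fell with level (r -0.503). Arrays 2 and 7 had a narrower signal range too (SD 1.80 each, DC scrambled mean 1.84). The slopes were not computed after normalization, so a shared narrower range cannot be told apart from gene-specific changes in common. Larger folds in arrays 1 and 5 may account for much of the size of the count. Without them 331 genes passed, 330 of them among the 9408, whereas leaving out any other pair labelled Hes3 siRNA left 5144 to 11607. The median fold change of the 9408 in the direction called moved from 0.266 (SD 0.102) to 0.189 (SD 0.0931). Their median SE moved from 0.0748 to 0.0798, and genes at an unadjusted p under 0.05 went from 11342 to 5827. The calls ended as folds became smaller, fewer degrees of freedom remained and the adjustment grew stricter, which were not tested apart. Part of the smaller folds follows from choosing the 9408 genes with these arrays included. A contribution of lower Hes3 mRNA cannot be told apart from its absence, because its probe set was 0.15 higher (log2) but lies at the 29.8th percentile of signal, where background can hide a decrease. Dim genes in general were higher there too, with a median of 0.146 in the dimmest of 4 equal parts.

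Within that count, 192 genes at least 1.5-fold lower in the DC arrays labelled Hes3 siRNA, Cldn1, Scgn, Edil3 and Chl1 among them, had a median log2 fold change of -0.657 before and -0.656 after quantile normalization, and all 192 still passed, 126 of them at 1.5-fold. The same correction took the count of all genes from 9408 to 5735. The folds of these 192 genes thus did not come from the part of the range that quantile normalization removes. They were chosen for their folds in the same arrays, so their passing again is no separate evidence of a difference. Without arrays 1 and 5 their median was -0.506 (median SE 0.128), 75 of the 192 passed and 31 did so at 1.5-fold, so the number at this size rests in part on those arrays. For the G2/M list, the median of -0.373 lay below random lists matched on level (-0.23 to -0.07) and was -0.315 without arrays 1 and 5, and it was -0.26 after cyclic loess normalization. These values argue against the range or those arrays alone as the cause. The random lists take no account of correlation among genes, estimated at 0.583 for this list. With an estimated correlation the adjusted p of the list was 0.479 by camera, and siRNA effects other than on Hes3 mRNA were not tested. A biological difference in mitosis between the labels stays open as a hypothesis found and tested on the same data.

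Among short RNA genes, 29 of 31 C/D box small nucleolar RNAs, which guide methylation of ribosomal RNA, were lower in the CC arrays labelled Hes3 siRNA (median -0.26, camera p = 5.64e-23, and p = 0.00461 with an estimated correlation; 0 passed limma alone, where 415 of all genes had an unadjusted p under 0.05). H/ACA small nucleolar RNAs were lower in 19 of 20 (median -0.13). Low values were not confined to CC. The C/D box median (log2 signal) was 8.51 and 8.70 in DC arrays 1 and 5 labelled Hes3 siRNA, and 9.11 and 9.30 in arrays 2 and 7. It was 8.96 to 9.04 in the DC scrambled arrays. Over the 12 arrays the C/D box median rose with that of the other short RNA genes (Pearson r 0.903, permutation p = 8e-05; Spearman rho 0.923, permutation p = 6e-05), with r = 0.8 without the 2 farthest arrays and r = 0.896 for deviations within groups. By class, r was 0.706 with H/ACA small nucleolar RNAs (20 genes; permutation p = 0.0212 adjusted over the 4 relations tested), 0.142 with scaRNAs (3 genes, 0.662) and 0.216 with Y and U RNAs (7 genes, 0.662). A difference in the yield of short RNA between preparations may account for the pattern, but it cannot be told apart from a difference in small nucleolar RNAs alone, since both other classes hold few genes. No biological explanation was tested.

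In 206 groups of 4 arrays, 11 values lay apart from the other 3 by Dixon's criterion, which chance gives in about 1 group in 20. Among the DC arrays labelled Hes3 siRNA, array 7 had Hes3 at 7.25 (others 7.36 to 7.38) and Ins2 at 12.86 (12.82 to 12.83). Array 1 of that group had Pirb at 8.01 (7.73 to 7.76) and Id1 at 7.94 (7.71 to 7.74), and array 5 had a hypoxia list median of 0.21 (-0.02 to 0.01). Among the DC scrambled arrays, array 1 had Mpv17l at 7.87 (7.96 to 7.98), Gpr6 at 7.80 (7.95 to 7.98) and Scd1 at 11.79 (11.76 to 11.77). Array 2 had the lowest SD over all probe sets, 1.82 (1.84 to 1.85), and array 3 had Gas5 at 10.72 (10.66 to 10.67) and an ER stress list median of -0.13 (-0.09 for the others).

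Effects of the siRNA label differed between DC and CC by camera for 8 lists, with median differences of -0.457 for G2/M, -0.294 for cholesterol synthesis, -0.264 for oxidative phosphorylation, -0.182 for ATF4 and amino acid genes, -0.148 for S phase, -0.115 for fatty acid synthesis, -0.111 for beta cell identity and 0.136 for Notch. With an estimated correlation none passed, the adjusted p running from 0.112 to 0.761. Outside the genes, 216 of 13767 probe sets without a single gene symbol passed limma between the culture conditions with scrambled siRNA, 122 higher and 94 lower in DC. The number was 3525 between the siRNA labels in DC, 3075 for culture in the arrays labelled Hes3 siRNA, and 0 in both other comparisons.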

How the results depend on the processing

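For culture with scrambled siRNA, Hmgcs1, Scd1, Lss, Fasn, Id1, Id2, Dusp6 and Agt kept direction and call in each alternative, and 11 of the 11 lists called did so after quantile and cyclic loess normalization. The dimmest genes lie near background, where small fold changes cannot be told from scaling. For what follows the cause was not tested, except that leaving out genes or arrays leaves less to test. Cyclic loess and leaving out DC arrays 1 and 5 labelled Hes3 siRNA were chosen after the data were seen.

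For genes between the siRNA labels in DC (9408), the count was 5735 after quantile normalization, 5436 with dim genes left out, 196 at 1.5-fold, 4297 after cyclic loess and 331 without arrays 1 and 5, where 21 of 122 named genes with a call kept it and 101 lost it. Leaving out each array gave 5754 to 10476. For culture with scrambled siRNA (1702) it was 1054 with array weights, 347 at 1.5-fold and 742 to 2364 leaving out each array. In the arrays labelled Hes3 siRNA (7986) it was 5025 after quantile normalization, 1103 at 1.5-fold, 5131 after cyclic loess, 3631 without arrays 1 and 5, and 2357 to 9516 leaving out each array. The difference of effects gave 0 to 2056 genes leaving out each array, and the siRNA labels in CC gave 0 in every alternative.

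Hes3 turned to -0.024 between the labels in DC after cyclic loess, and for culture in the arrays labelled Hes3 siRNA to -0.031 after quantile normalization and -0.073 after cyclic loess. Leaving out each array it ran from -0.006 to 0.406 between the labels in CC, 0.12 to 0.18 in DC, -0.04 to 0.371 for culture with scrambled siRNA, and -0.256 to 0.155 for the difference. The correlation of siRNA effects was 0.146 with dim genes left out and ran from -0.381 to 0.717, and that of culture effects from 0.287 to 0.858.

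Quantile normalization turned the sign of Pdx1 between the labels in CC (-0.012), of Ins2 in DC (0.016), of Ins2 (0.053) and Pdx1 (0.030) for culture under the Hes3 siRNA label and of Ins2 in the difference (0.015). Centring turned Ins2 for culture with scrambled siRNA (-0.005) and Mafa under the Hes3 siRNA label (-0.066). Cyclic loess turned Ins2 (-0.054) and Pdx1 (-0.001) in CC, Ins2 (0.081), Mafa (0.001) and Rbp4 (-0.007) in DC, Ins2 (0.185) and Pdx1 (0.018) for culture under the Hes3 siRNA label, and Ins2 in the difference (0.135). Leaving out each array, the range in CC was -0.017 to 0.040 for Ins2, -0.042 to 0.094 for Pdx1 and -0.138 to 0.182 for Mafa. It was -0.008 to 0.129 for Pdx1 in culture with scrambled siRNA, and -0.043 to 0.131 for Mafa and -0.068 to 0.045 for Hes1 under the Hes3 siRNA label. Of these only Rbp4 was called on the deposited scale.

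Lists past camera for the siRNA labels in CC (7) numbered 4 with dim genes left out, 0 with an estimated correlation, 0 by fry and 2 to 7 leaving out each array. In DC (15) they numbered 9 after quantile normalization, 0 with an estimated correlation, 20 by fry and 1 after cyclic loess, where G2/M alone remained. Of these 15 calls, 5 were lost with dim genes left out, ATF4 among them (adjusted p = 0.0645 by camera), and 4 without arrays 1 and 5. For culture they numbered 4 of 11 with scrambled siRNA and 1 of 9 under the Hes3 siRNA label with an estimated correlation, and 10 and 13 by fry. For the difference (8) they numbered 5 after quantile normalization, 0 with an estimated correlation, 1 by fry and 4 after cyclic loess. List medians that turned included macrophage and endothelial in DC with dim genes left out (-0.085), and after cyclic loess beta cell identity (0.034) and ER stress (0.055) in DC and beta cell identity in the difference (0.058). After quantile normalization those of ER stress in DC and of beta cell identity in the difference turned as well. That of insulin granule in CC turned without CC scrambled array 2. Leaving out each array in CC, the median ran from -0.036 to 0.239 for G2/M, -0.033 to 0.137 for cholesterol synthesis, -0.025 to 0.255 for oxidative phosphorylation and -0.028 to 0.188 for fibroblast markers.

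With replicate number as a block, 620 genes passed between the labels in DC, 804 for culture with scrambled siRNA and 4051 under the Hes3 siRNA label, and Mafa was 0.026 in DC and 0.003 in the difference. Numbers 3, 4, 5 and 7 each occur on a single array, so the block fits those DC arrays exactly and they add nothing to these counts. The smaller counts therefore partly reflect fewer usable arrays and do not test pairing. Nothing in the labels says that the numbers pair the arrays, and the data do not decide it. Deviations of arrays that share a number correlated at -0.441 to 0.536, with 0.253 in CC and -0.368 and -0.327 in DC. In CC the value is the same for numbers 1 and 2 by construction, since the deviations of 2 arrays in a group mirror each other.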

Other observations

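Of the tests in this part, all were chosen after the results that prompted them were seen.

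ERK feedback genes other than Dusp6 were lower in DC with scrambled siRNA in 11 of 11 measured members, and 4 of them fell: the transcription factors Etv5 (log2 fold change -0.76 ± 0.0848 SE, 4 arrays against 2) and Etv4 (-0.46 ± 0.0849), the phosphatase Dusp5 (-0.55 ± 0.0963) and Spry4 (-0.42 ± 0.0864). Their median of -0.282 lay below random lists matched on level (-0.14 to 0.10), and in the arrays labelled Hes3 siRNA it was -0.38, with 10 of 11 lower and 8 past the test. The random lists take no account of correlation among feedback genes, and camera was not run on this list. Less ERK signalling in DC is a candidate explanation for the lower Dusp6, as a hypothesis found on the same data, and the medium, serum and oxygen cannot be separated here.

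Both other hypotheses stayed undecided. Less BMP/SMAD signalling could account for lower Id1, Id2 and Id3, and the other 8 target genes had a median of -0.117 with scrambled siRNA, just below random lists (-0.114 to 0.105), but 0.03 in the arrays labelled Hes3 siRNA. Of these 8 only Smad7 (-0.50 ± 0.0785) and Hey1 (-0.53 ± 0.120) fell with scrambled siRNA. In the arrays labelled Hes3 siRNA 3 of the 8 fell, Hey1 (-0.77 ± 0.120), Smad9 (-0.36 ± 0.0824) and Smad7 (-0.23 ± 0.0785), and 0 rose. Abca1, a cholesterol exporter and LXR target, was higher in DC with scrambled siRNA (1.24 ± 0.188), and more LXR activity could account for it, but the other 8 target genes had a median of 0.045, inside the range of random lists (-0.17 to 0.11), with Srebf1 (0.86 ± 0.0815) and Mylip (0.27) among 3 that rose and Smpdl3a (-0.33) the 1 that fell. In the arrays labelled Hes3 siRNA Abca1 was higher in DC too (0.60 ± 0.188). There the other 8 had a median of 0.153, just inside the range of random lists (-0.347 to 0.157), with 2 that rose and 1 that fell.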
